A study of Mus musculus with 21 samples.

How the data were processed

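RNA sequencing of mouse liver (7 libraries) and of RAW264.7 cells (6 libraries at 24 h and 8 at 12 h) was analysed from the values that the study provides. The deposited values are TPM per gene symbol, which the authors made with Salmon on the builds mm10 and GRCm38 per the submitters' processing notes, without stated versions or annotation. Libraries were made with a stranded mRNA kit. TPM are scaled within each library and hold no read counts, so the depth of a library, and the counting error that depth sets, are unknown. The cell line values list 35550 genes, and TPM sum to between 993386.5 and 999190.5 per library. The liver values are rounded to 2 decimals and sum to between 153179.8 and 336332.5, since only genes at least 2-fold apart between the WT LPS and PBS libraries are listed there. The reads were not used here.

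Groups follow the labels by genotype, treatment, time and tissue, with 2 libraries per cell line group and 1 per liver group. At 24 h the LPS and CTM libraries carry the numbers 2 and 3 in the values and 1 and 2 in the labels, so they were assigned to a group and not to a labelled replicate. RNA of liver was extracted on 3 dates, with TG2-KO on a date of its own. A macrophage-depleted group without LPS, which the study text mentions, was not analysed here. Levels were tested only within the 24 h experiment or within the 12 h experiment.

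Cell line genes with a mean of at least 1 TPM over the libraries of an experiment were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3. All groups of the experiment shared 1 linear model with a mean-variance trend, and Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. The interaction is the LPS change in Vim-KO minus that in WT cells. Gene lists were tested with camera at its preset correlation between genes of 0.01, for lists with at least 3 members tested. Camera with an estimated correlation and fry, both of the limma package, were run as alternatives. Members of a list were also adjusted over the list alone. For liver, the difference of log2(TPM + 1) is given without a test, genes differing by at least 1 are counted, and the median of a list is placed among 10000 random lists of the same size matched on mean expression in 20 bins. Lists between the percentiles 2.5 and 97.5 were not described. Relations between comparisons were computed with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.

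The groups, the tests, the gene lists (36 for the cell line and 51 for liver, of which 37 had at least 3 members), the rule for naming genes and most alternatives were fixed before the data were examined. The rule names Vim and Tgm2 and the 6 highest and 6 lowest changes past the threshold, with no overlap between the groups and at least 5 TPM in the higher group, skipping predicted genes. It adds up to 4 members with the largest change of each list described. For liver the higher library needs at least 10 TPM, and Kupffer cell markers are named for depletion. The text gives part of the genes that the rule names. Gene positions are those of a GRCm38 annotation and may differ from the one behind the values. Close paralogs such as Hspa1a and Hspa1b, Saa1 and Saa2, or Mx1 and Mx2 share reads, and how these were divided is not stated.

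Alternatives were a pseudocount of 0.1, no filter or a filter at 5 TPM, median-of-ratios scaling between libraries, limma without the trend, a fit on the samples of the contrast alone, a replicate block at 12 h and for CTM against LPS at 24 h, leaving out each library in turn, and an added minimum log2 change of 1. For liver the minimum was 2. The model was tested on simulated data with 200 changed genes. At 24 h it called 86% of genes changed by 1 and 99% of genes changed by 2 on the log2 scale, with 6 false among 191 calls. At 12 h these were 94%, 100% and 15 of 209. Within groups the log2 values of the 2 libraries correlated at 0.986 to 0.990, and the SD of their differences was 0.287 to 0.34.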

Results

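RNA sequencing expression values of 21 mouse libraries were analysed, as TPM (the unit of transcript abundance that the files hold). The liver had 7 groups of 1 library each (wild type with PBS, LPS, LPS plus CTM, and LPS with or without macrophage depletion, and TG2-KO with PBS or LPS), and so no replicates. RAW264.7 cells, a mouse macrophage-like line, held 3 groups at 24 h (PBS, LPS, LPS plus CTM) and 4 groups at 12 h (wild type and Vim-KO, each with PBS or LPS), with 2 libraries per group. LPS is an outer membrane component of Gram-negative bacteria that activates macrophages, and CTM is named here as the labels give it. Mice received LPS at 30 mg/kg (no dose is given for the depletion pair) and CTM at 100 mg/kg, and cells LPS at 1 µg/mL and CTM at 0.5 mM. TPM keep no read depth, so the depth of each library is unknown. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Cell line values are mean ± SD in TPM (n = 2 per group), fold changes are on the log2 scale ± SE, and adjusted p are from limma (genes) or camera of the limma package (lists). A gene named as changed had no overlap between its groups.

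The targeted genes were read first. Vim, which encodes the intermediate filament protein vimentin, lies on chromosome 2 from 13573927 to 13582826 (GRCm38), and Tgm2, which encodes transglutaminase 2, on chromosome 2 from 158116402 to 158146436. In the 12 h experiment Vim stood at 1930 and 1877 TPM in the WT PBS libraries and at 1375 and 1461 TPM in the WT LPS libraries. The Vim-KO libraries held 16.99 and 18.7 TPM with PBS and 30.8 and 33.0 TPM with LPS, which is 0.94% and 2.25% of the WT level. Liver Tgm2 was 0.74 TPM (PBS) and 15.5 TPM (LPS) in the TG2-KO libraries. The WT livers held 35.7 TPM with PBS, 424.8 TPM with LPS, 429 TPM with LPS plus CTM, and 382 and 351 TPM without and with macrophage depletion. In the 24 h experiment Vim was 419.7 and 442 TPM with PBS, 738 and 739 TPM with LPS, and 539.6 and 597 TPM with LPS plus CTM. Tgm2 was 15.7 and 20.96 TPM with PBS, 72.2 and 67.4 TPM with LPS, and 32.6 and 32.3 TPM with LPS plus CTM. At 12 h Tgm2 was low, between 3.11 and 3.39 TPM in the WT libraries and between 0.051 and 0.55 TPM in the Vim-KO libraries.

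**Figure D1:**
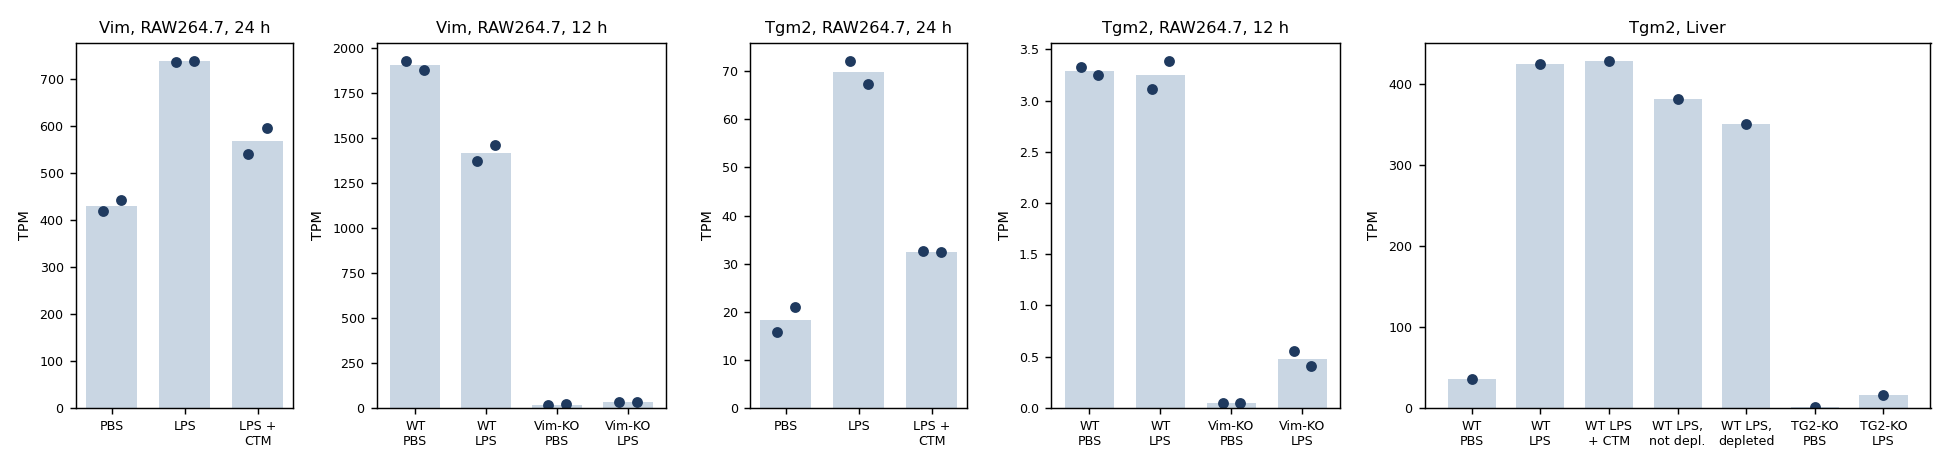
Vim and Tgm2 levels in TPM per group; bars are group means, points are libraries, and liver groups hold 1 library each. Vim is 0.94% of the WT level in Vim-KO cells with PBS, and Tgm2 is 0.74 TPM in the TG2-KO liver with PBS.

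LPS against PBS at 24 h asks what macrophage activation does to these cells. Inflammatory mediators rose most. The neutrophil chemokine Cxcl2 (3893 ± 268 against 4.55 ± 0.234 TPM, log2 fold change 9.45 ± 0.12, adjusted p = 1.21e-08), the pyrogenic cytokine Il1b (977 ± 12.2 against 2.33 ± 0.7503 TPM, log2 fold change 8.21 ± 0.15, adjusted p = 4.56e-08) and Ptgs2 (865 ± 7.22 against 4.1958 ± 0.691 TPM, log2 fold change 7.39 ± 0.13, adjusted p = 3.96e-08), which encodes the inducible prostaglandin synthase, were among the 6 highest changes. Csf3, the granulocyte growth factor, was listed at 0 in both PBS libraries and at 749.6 and 805 TPM with LPS, and Il1a at 0 with PBS and at 289 and 300.1 TPM with LPS. The iron-sequestering lipocalin Lcn2 (156 ± 9.46 against 0.103 ± 0.146 TPM, log2 fold change 7.16 ± 0.12) rose as well. The largest decreases included Hpgd (4.53 ± 0.0917 against 162 ± 2.11 TPM, log2 fold change -4.88 ± 0.09, adjusted p = 5.08e-08), which degrades prostaglandins, Txnip (19.5 ± 4.48 against 355 ± 4.52 TPM, log2 fold change -4.13 ± 0.13), an inhibitor of thioredoxin, and Clec7a (2.17 ± 0.0793 against 32.4 ± 6.08 TPM, log2 fold change -3.39 ± 0.17), the beta-glucan receptor. Both genes of the study rose, Vim (738 ± 1.32 against 431 ± 15.6 TPM, log2 fold change 0.78 ± 0.058, adjusted p = 2.83e-05) and Tgm2 (69.8 ± 3.39 against 18.4 ± 3.69 TPM, log2 fold change 1.88 ± 0.13, adjusted p = 1.87e-05).

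Of the inflammatory cytokines and chemokines, 22 of 24 rose, 1 fell and 1 did not pass (23 and 1 adjusted over the list alone, camera adjusted p = 5.49e-17; adjusted p = 0.102 with an estimated correlation). Among genes of classical activation 15 of 15 rose (15 adjusted over the list alone, camera adjusted p = 3.85e-13; adjusted p = 0.102 with an estimated correlation). Nos2 (194 ± 11.5 against 1.73 ± 0.505 TPM), which makes nitric oxide, and Acod1 (1669 ± 26.97 against 68.1 ± 6.704 TPM), which makes itaconate, rose. Type I interferon-stimulated genes went the same way: 31 of 34 rose and 3 did not pass (31 adjusted over the list alone, camera adjusted p = 6.3e-19; adjusted p = 0.102 with an estimated correlation). Irf7 (654 ± 8.196 against 36.5 ± 1.002 TPM) and Isg15 (113 ± 0.433 against 7.76 ± 0.635 TPM) rose. In the ATF4 and amino acid response 22 of 26 rose, 2 fell and 2 did not pass (22 and 2 adjusted over the list alone, camera adjusted p = 2.77e-13; adjusted p = 0.102 with an estimated correlation). Atf3 (547 ± 14.5 against 12.7 ± 3.7 TPM), the cystine transporter Slc7a11 (196 ± 11.2 against 8.76 ± 0.236 TPM) and Ddit3 (154 ± 11.8 against 14.5 ± 0.805 TPM) rose. Among p53 targets 17 of 19 rose and 2 fell (17 and 2 adjusted over the list alone, camera adjusted p = 7.88e-10; adjusted p = 0.102 with an estimated correlation).

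Genes of protein turnover moved in several directions. Of the lysosome list 23 of 34 rose, 7 fell and 4 did not pass (23 and 7 adjusted over the list alone, camera adjusted p = 2.45e-06; adjusted p = 0.102 with an estimated correlation). After scaling 26 rose and 3 fell. In the autophagy list 14 of 27 rose, 4 fell and 9 did not pass (14 and 4 adjusted over the list alone, camera adjusted p = 6.77e-05; adjusted p = 0.204 with an estimated correlation). After scaling 18 rose and 1 fell. The cargo receptor Sqstm1 (1855 ± 68.6 against 164 ± 1.02 TPM) rose most. The immunoproteasome and MHC class I list was higher, in which 13 rose, 1 fell and 3 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 1e-06; adjusted p = 0.102 with an estimated correlation). B2m (2027 ± 44.4 against 1052 ± 5.67 TPM) and H2-T23 (111 ± 8.196 against 30.9 ± 2.32 TPM) rose. Of the 33 constitutive proteasome genes 8 rose and 13 fell, a balance that turned to 18 rising and 3 falling after median-of-ratios scaling (camera adjusted p = 0.455, direction up, where the median change was -0.065). Heat shock genes, of which 2 rose, 12 fell and 5 did not pass (2 and 12 adjusted over the list alone), did not pass as a list (camera adjusted p = 0.153). After scaling 5 rose and 8 fell. Hspa8 (864 ± 15.8 against 1559 ± 13.3 TPM) and Dnaja1 (142 ± 9.49 against 322 ± 0.147 TPM) fell.

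Cell division genes fell. Of the S phase list 23 of 24 fell and 1 did not pass (23 adjusted over the list alone, camera adjusted p = 2.04e-07; adjusted p = 0.339 with an estimated correlation). Of the G2 and M phase list 23 of 24 fell and 1 did not pass (23 adjusted over the list alone, camera adjusted p = 3.16e-07; adjusted p = 0.339 with an estimated correlation). Tk1 (41.6 ± 2.57 against 198 ± 7.16 TPM) and Mki67 (49.9 ± 3.25 against 159.9 ± 10.1 TPM) fell. In cholesterol biosynthesis 1 of 24 rose, 17 fell and 6 did not pass (1 and 17 adjusted over the list alone, camera adjusted p = 6.71e-03; adjusted p = 0.424 with an estimated correlation). Hmgcs1 (18.6 ± 0.998 against 52.2 ± 0.662 TPM) fell. Of the mitochondrially encoded transcripts 12 of 13 fell and 1 did not pass (12 adjusted over the list alone, camera adjusted p = 6.95e-05; adjusted p = 0.339 with an estimated correlation). In total 7277 of 11030 genes passed, 2300 higher and 4977 lower, and 853 and 1443 of them changed at least 2-fold. The median fold change of all genes lay -0.24 from that after median-of-ratios scaling, and 31.6% of the genes past the threshold were higher as listed against 50.9% after scaling.

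LPS plus CTM against LPS at 24 h asks how the compound alters the activated state. Many genes that LPS raised were lower with CTM. The largest decreases were the cytokines Lif (7.54 ± 2.41 against 77.9 ± 3.64 TPM, log2 fold change -3.24 ± 0.20, adjusted p = 2.98e-04), Il1a (33.7 ± 6.86 against 294 ± 7.88 TPM, log2 fold change -3.10 ± 0.14, adjusted p = 1.39e-04) and Il6 (2.6971 ± 1.09 against 22.8 ± 1.37 TPM, log2 fold change -2.72 ± 0.22, adjusted p = 5.53e-04). Ptgs2 (142 ± 23.9 against 865 ± 7.22 TPM, log2 fold change -2.61 ± 0.13, adjusted p = 1.6e-04), the G protein regulator Rgs1 (32.3 ± 5.004 against 173 ± 14.4 TPM, log2 fold change -2.39 ± 0.13) and the growth arrest gene Gadd45g (3.35 ± 0.758 against 20.2 ± 2.701 TPM, log2 fold change -2.29 ± 0.18) came next. The largest increases held the pro-apoptotic BH3 gene Bmf (6.61 ± 0.486 against 1.34 ± 0.236 TPM, log2 fold change 1.70 ± 0.14, adjusted p = 5.53e-04) and Lfng (13.8 ± 1.66 against 3.72 ± 0.799 TPM, log2 fold change 1.65 ± 0.15), which modifies Notch receptors. Ccne2 (9.64 ± 2.36 against 2.58 ± 0.264 TPM, log2 fold change 1.56 ± 0.17), a cyclin of S phase entry, also rose. Vim fell (568 ± 40.5 against 738 ± 1.32 TPM, -0.38 ± 0.058, adjusted p = 4.55e-03), and so did Tgm2 (32.5 ± 0.232 against 69.8 ± 3.39 TPM, -1.08 ± 0.13, adjusted p = 1.89e-03).

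Cytokines and chemokines were lower, and in that list 20 of 24 fell and 4 did not pass (22 adjusted over the list alone, camera adjusted p = 1.18e-19; adjusted p = 0.223 with an estimated correlation). Il1b (209 ± 23.9 against 977 ± 12.2 TPM) was lower with CTM. Among NF-kB feedback and target genes 15 of 21 fell and 6 did not pass (1 higher and 16 lower adjusted over the list alone, camera adjusted p = 9.14e-10; adjusted p = 0.291 with an estimated correlation). Genes of classical activation followed, of which 10 fell and 5 did not pass (11 adjusted over the list alone, camera adjusted p = 8.79e-08; adjusted p = 0.227 with an estimated correlation). Of the type I interferon-stimulated genes 1 of 34 rose, 15 fell and 18 did not pass (1 and 16 adjusted over the list alone, camera adjusted p = 4.7e-07; adjusted p = 0.3 with an estimated correlation). Rsad2 (3.6957 ± 0.106 against 14.9 ± 0.441 TPM) and Isg20 (11.2 ± 1.11 against 32.024 ± 2.65 TPM) were lower with CTM. Among p53 targets 2 of 19 rose, 12 fell and 5 did not pass (2 and 13 adjusted over the list alone, camera adjusted p = 4.17e-07; adjusted p = 0.223 with an estimated correlation). Mdm2 (147 ± 17.1 against 383 ± 28.4 TPM) was lower with CTM. Within immediate early genes 2 of 19 rose, 10 fell and 7 did not pass (3 and 11 adjusted over the list alone, camera adjusted p = 5.06e-05; adjusted p = 0.333 with an estimated correlation). Nr4a1 (8.1963 ± 2.198 against 43.6 ± 7.57 TPM) and Dusp1 (16.6 ± 5.04 against 72.2 ± 4.7 TPM) were lower with CTM.

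Chaperones of the endoplasmic reticulum rose with CTM. In that list 18 of 25 rose, 1 fell and 6 did not pass (18 and 1 adjusted over the list alone, camera adjusted p = 1.19e-07; adjusted p = 0.324 with an estimated correlation). The secreted factor Manf (569 ± 41.7 against 309 ± 34.7 TPM, log2 fold change 0.88 ± 0.083, adjusted p = 8.22e-04), Sdf2l1 (298 ± 9.58 against 164 ± 8.21 TPM) and Creld2 (139 ± 3.303 against 82.6 ± 1.89 TPM) were higher with CTM. Of the heat shock genes, mostly cytosolic, 9 of 19 rose, 1 fell and 9 did not pass (9 and 1 adjusted over the list alone, camera adjusted p = 0.0131; adjusted p = 0.324 with an estimated correlation). The co-chaperone Fkbp4 (199 ± 5.46 against 127 ± 3.64 TPM) and the mitochondrial chaperonin Hspd1 (613 ± 4.21 against 425 ± 13.01 TPM) were higher. Hspa1b (1.19 ± 0.407 against 5.58 ± 1.496 TPM), whose reads may be shared with Hspa1a, was lower. The AAA ATPase gene Vcp (267 ± 7.94 against 168 ± 8.898 TPM, log2 fold change 0.67 ± 0.063, adjusted p = 8.64e-04), which extracts ubiquitinated proteins, rose. Autophagy genes were lower, of which 11 fell and 16 did not pass (15 adjusted over the list alone, camera adjusted p = 4.05e-07; adjusted p = 0.223 with an estimated correlation). Lysosome genes were lower as well, of which 2 rose, 12 fell and 20 did not pass (2 and 14 adjusted over the list alone, camera adjusted p = 1.75e-05; adjusted p = 0.223 with an estimated correlation). Sqstm1 (1136 ± 56.2 against 1855 ± 68.6 TPM), Nbr1 (48.4 ± 1.23 against 85.7 ± 0.0833 TPM) and Gpnmb (143 ± 20.2 against 278 ± 6.83 TPM) were lower with CTM.

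Of the S phase genes 18 of 24 rose, 1 fell and 5 did not pass (20 and 1 adjusted over the list alone, camera adjusted p = 5.55e-07; adjusted p = 0.333 with an estimated correlation). After scaling 12 rose and 1 fell. Cdc6 (7.22 ± 0.616 against 3.06 ± 0.293 TPM) and Tk1 (78.7 ± 1.89 against 41.6 ± 2.57 TPM) were higher with CTM. In cholesterol biosynthesis 8 of 24 rose, 1 fell and 15 did not pass (12 and 1 adjusted over the list alone, camera adjusted p = 2.21e-03; adjusted p = 0.373 with an estimated correlation). Sqle (41.3 ± 0.686 against 26.3 ± 2.76 TPM) was higher with CTM. In total 2823 genes passed, 1781 higher and 1042 lower, of which 84 and 170 changed at least 2-fold. With median-of-ratios scaling 45.3% of the genes past the threshold were higher, against 63.1% as listed. The count depends on single libraries. It was 1680 without 1 of the LPS libraries, and 1525 and 1094 without either CTM library.

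**Figure D2:**
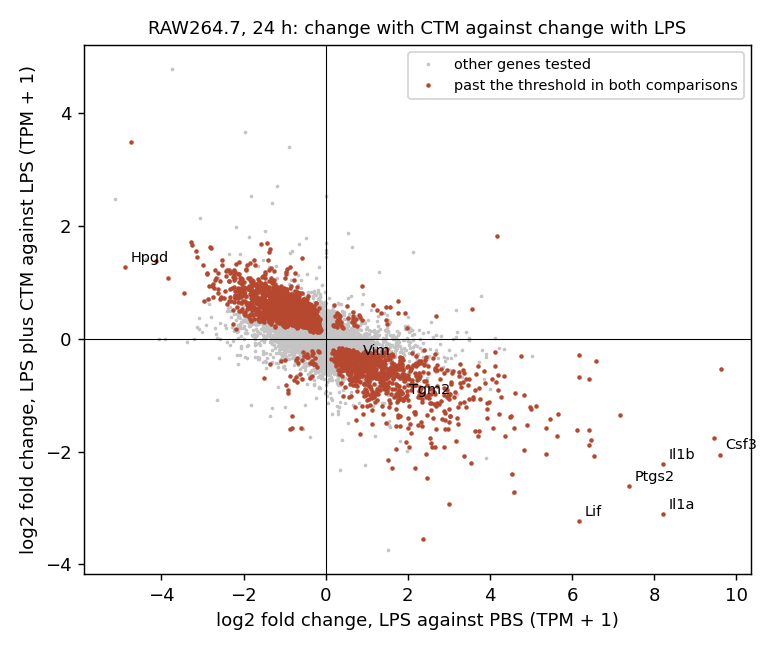
Each point is a gene of the 24 h experiment, with the log2 fold change of LPS against PBS on the horizontal axis and that of LPS plus CTM against LPS on the vertical axis. Of the genes past the threshold in both, 2450 lie on opposite sides of 0 and 87 on the same side, and both axes use the same LPS libraries.

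Because both contrasts share the LPS libraries, their relation was set against simulations. Of genes past both thresholds, 856 were raised by LPS and lowered by CTM and 1594 were lowered and then raised. After scaling these were 1319 and 1035, so the balance of directions turns. The other 47 and 40 genes moved the same way in both. Across genes (not independent replicates) Pearson's r was -0.684, against -0.495 in 100 simulations without an LPS or CTM effect. With no LPS effect, they give no baseline of r or signs for CTM alone. The covariance was -0.275 against -0.028, and 77.1% against 66.7% of genes had opposite signs. With 1 LPS library given to each contrast r was -0.559 or -0.569.

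LPS plus CTM against PBS at 24 h mixes both, as no group had CTM alone. Inflammatory genes stayed above PBS: Cxcl2 (1160.5 ± 213 against 4.55 ± 0.234 TPM, log2 fold change 7.70 ± 0.12, adjusted p = 5.7e-08), Il1b (209 ± 23.9 against 2.33 ± 0.7503 TPM, log2 fold change 5.99 ± 0.15, adjusted p = 3.77e-07) and Lcn2 (60.7 ± 5.42 against 0.103 ± 0.146 TPM, log2 fold change 5.81 ± 0.12) were among the highest, and Csf3 stood at 199.8 and 174 TPM, listed at 0 with PBS. Hpgd (12.3 ± 0.821 against 162 ± 2.11 TPM, log2 fold change -3.61 ± 0.09), Clec7a (2.05 ± 0.295 against 32.4 ± 6.08 TPM, log2 fold change -3.44 ± 0.17) and Tmem176a (14.8 ± 1.22 against 122 ± 28.6 TPM, log2 fold change -2.93 ± 0.17) were among the lowest. Vim (568 ± 40.5 against 431 ± 15.6 TPM) and Tgm2 (32.5 ± 0.232 against 18.4 ± 3.69 TPM) were higher than with PBS, at 0.40 ± 0.058 and 0.80 ± 0.13. Among inflammatory cytokines and chemokines 19 of 24 rose, 1 fell and 4 did not pass (20 and 1 adjusted over the list alone, camera adjusted p = 1.28e-14; adjusted p = 0.112 with an estimated correlation). Among type I interferon-stimulated genes 30 of 34 rose and 4 did not pass (31 adjusted over the list alone, camera adjusted p = 3.39e-21; adjusted p = 0.107 with an estimated correlation). In the ATF4 and amino acid response 25 of 26 rose and 1 did not pass (25 adjusted over the list alone, camera adjusted p = 3.39e-21; adjusted p = 0.107 with an estimated correlation). Trib3 (53.2 ± 1.68 against 1.49 ± 1.101 TPM) and Chac1 (27.6 ± 0.2904 against 1.26 ± 0.288 TPM) rose. Of the NRF2 targets 15 of 23 rose, 2 fell and 6 did not pass (15 and 3 adjusted over the list alone, camera adjusted p = 3.99e-08; adjusted p = 0.107 with an estimated correlation). Hmox1 (509 ± 24.1 against 90.959 ± 4.52 TPM) rose. S phase genes remained lower, in which 22 fell and 2 did not pass (23 adjusted over the list alone, camera adjusted p = 1.79e-08; adjusted p = 0.301 with an estimated correlation). Of the 11030 genes 5839 passed, 1922 higher and 3917 lower, with 540 and 689 at least 2-fold. Of the genes past the threshold 32.9% were higher as listed and 53.3% after scaling, with the medians -0.16 apart.

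LPS against PBS in WT cells at 12 h gives the reference response of the Vim experiment. Il1b (2749.5 ± 34.1 against 0.372 ± 0.0309 TPM, log2 fold change 10.97 ± 0.07, adjusted p = 6.74e-11) was the largest change. Il1a (1858 ± 35.8 against 0.203 ± 0.166 TPM, log2 fold change 10.60 ± 0.12), Csf3 (1464 ± 90.5 against 0.0626 ± 0.0886 TPM, log2 fold change 10.43 ± 0.11), Cxcl2 (2356 ± 36.3 against 0.899 ± 0.509 TPM, log2 fold change 10.30 ± 0.16) and Lcn2 (3566 ± 349.7 against 2.73 ± 0.584 TPM, log2 fold change 9.91 ± 0.15) followed. The lowest held Igfbp4 (1.36 ± 0.645 against 60.1 ± 0.457 TPM, log2 fold change -4.72 ± 0.18, adjusted p = 2.72e-07), which binds insulin-like growth factors, and Itgb5 (7.16 ± 1.59 against 137 ± 0.218 TPM, log2 fold change -4.09 ± 0.12), an integrin chain. Cldn11 (1.68 ± 0.0877 against 77.3 ± 6.52 TPM, log2 fold change -4.86 ± 0.10), a claudin, and Hpgd (0.44986 ± 0.04101 against 31.6 ± 1.32 TPM, log2 fold change -4.49 ± 0.15) fell too. Vim fell in these cells (1418 ± 61.2 against 1904 ± 37.6 TPM, -0.43 ± 0.069, adjusted p = 7.71e-04), and Tgm2 did not pass (3.25 ± 0.196 against 3.29 ± 0.06002 TPM, adjusted p = 0.94).

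Of the inflammatory cytokines and chemokines 24 of 26 rose, 1 fell and 1 did not pass (24 and 1 adjusted over the list alone, camera adjusted p = 1.57e-23; adjusted p = 0.036 with an estimated correlation). In the type I interferon-stimulated list 29 of 34 rose, 1 fell and 4 did not pass (29 and 1 adjusted over the list alone, camera adjusted p = 9.79e-18; adjusted p = 0.036 with an estimated correlation). All of the constitutive proteasome genes rose: 33 of 33 rose (33 adjusted over the list alone, camera adjusted p = 7.38e-18; adjusted p = 0.0492 with an estimated correlation). Psma6 (1001 ± 45.1 against 274 ± 1.51 TPM) and Psmd11 (318 ± 9.75 against 144 ± 6.61 TPM) rose. Of the endoplasmic reticulum chaperones 20 of 25 rose, 3 fell and 2 did not pass (21 and 3 adjusted over the list alone, camera adjusted p = 5.88e-11; adjusted p = 0.108 with an estimated correlation). The luminal chaperone Hspa5 (2263 ± 14.2 against 927 ± 34.2 TPM) and Herpud1 (117 ± 5.59 against 29.3 ± 1.24 TPM) rose. Actin and adhesion genes moved too, of which 15 rose, 3 fell and 5 did not pass (15 and 3 adjusted over the list alone, camera adjusted p = 1.71e-07; adjusted p = 0.271 with an estimated correlation). Actg1 (4996 ± 379.8 against 771 ± 28.3 TPM) and Zyx (111 ± 18.8 against 18.4 ± 0.0883 TPM) rose. In the immunoproteasome and MHC class I list 1 member rose and 12 fell (camera adjusted p = 0.173). After scaling 4 rose and 8 fell. Psmb9 (13.8 ± 0.437 against 53.4 ± 4.64 TPM) and Psmb8 (140.3 ± 1.54 against 250.3 ± 1.55 TPM) fell.

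Proliferation genes fell together, and of the G2 and M phase list 24 of 24 fell (24 adjusted over the list alone, camera adjusted p = 1.13e-10; adjusted p = 0.115 with an estimated correlation). Ccnb2 (15.7 ± 1.04 against 187 ± 1.82 TPM) and Plk1 (12.7 ± 0.311 against 123 ± 9.896 TPM) fell. Of the S phase list 24 of 24 fell (24 adjusted over the list alone, camera adjusted p = 2.64e-07; adjusted p = 0.0466 with an estimated correlation). Among oxidative phosphorylation genes 1 of 31 rose, 26 fell and 4 did not pass (1 and 26 adjusted over the list alone, camera adjusted p = 2.62e-03; adjusted p = 0.186 with an estimated correlation), a camera call that ended with scaling (adjusted p = 0.0696), where 5 rose and 14 fell, with Sdha (84.5 ± 5.96 against 206 ± 3.15 TPM). In all 7881 of 11115 genes passed, 1983 higher and 5898 lower, 704 and 2008 of them at least 2-fold. The median as listed lay -0.35 from that after scaling, and the share of higher genes among those past the threshold was 25.2% as listed and 51.3% after scaling. Heat shock genes, 5 rising and 8 falling as listed, turned to 12 rising and 5 falling after scaling.

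LPS against PBS in Vim-KO cells asks what the response looks like without vimentin. Cxcl2 (4514 ± 296 against 0.944 ± 0.0646 TPM, log2 fold change 11.18 ± 0.16, adjusted p = 3e-09), Lcn2 (1628 ± 233 against 0.772 ± 0.253 TPM, log2 fold change 9.84 ± 0.15), Il1b (559.5 ± 9.95 against 0.037014 ± 0.0523 TPM, log2 fold change 9.08 ± 0.07, adjusted p = 2.95e-10) and Ptgs2 (2237 ± 279 against 3.9969 ± 0.116 TPM, log2 fold change 8.80 ± 0.09) were among the largest increases, and Csf3 went from 0 in both PBS libraries to 1381 and 1134 TPM. The lowest were the lysosomal glycoprotein Gpnmb (11.1 ± 0.297 against 408 ± 16.8 TPM, log2 fold change -5.08 ± 0.08, adjusted p = 4.8e-09), and Rgs2 (0.946 ± 0.321 against 47.4 ± 3.59 TPM, log2 fold change -4.64 ± 0.12), a G protein regulator. Emp1 (2.97 ± 0.1296 against 87.1 ± 7.84 TPM, log2 fold change -4.47 ± 0.097), a membrane protein, and Ranbp3l (9.09 ± 1.104 against 215 ± 21.4 TPM, log2 fold change -4.42 ± 0.13) fell too. The remaining Vim signal rose (31.9 ± 1.55 against 17.8 ± 1.19 TPM, 0.80 ± 0.069, adjusted p = 2.24e-05), and Tgm2 was 0.47984 ± 0.0996 against 0.0511 ± 0.000429 TPM (0.49 ± 0.15, adjusted p = 0.0197).

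Every type I interferon-stimulated gene rose: 34 of 34 rose (34 adjusted over the list alone, camera adjusted p = 6.87e-29; adjusted p = 0.0264 with an estimated correlation). Rsad2 (106 ± 4.04 against 0.676 ± 0.00224 TPM), Ifit3 (103 ± 3.99 against 0.689 ± 0.424 TPM), whose reads may be shared with Ifit3b, and Isg15 (303 ± 1.14 against 4.02 ± 0.525 TPM) rose. In the list of cytokines and chemokines 23 of 26 rose, 1 fell and 2 did not pass (23 and 1 adjusted over the list alone, camera adjusted p = 8.19e-17; adjusted p = 0.0346 with an estimated correlation). Among guanylate-binding proteins and immunity-related GTPases, which act against intracellular pathogens, 10 of 10 rose (10 adjusted over the list alone, camera adjusted p = 2.26e-07; adjusted p = 0.0346 with an estimated correlation). Igtp (33.8 ± 1.803 against 3.91 ± 0.124 TPM) rose. In the p53 list 16 of 19 rose, 1 fell and 2 did not pass (16 and 1 adjusted over the list alone, camera adjusted p = 7.67e-10; adjusted p = 0.0893 with an estimated correlation). The cell cycle inhibitor Cdkn1a (1486 ± 91.3 against 229 ± 0.0648 TPM) and Fas (13.7 ± 0.0441 against 0.469 ± 0.285 TPM) rose. Of the constitutive proteasome genes 26 of 33 rose and 7 did not pass (26 adjusted over the list alone, camera adjusted p = 2.25e-09; adjusted p = 0.101 with an estimated correlation). The G2 and M phase list fell, where 24 fell (24 adjusted over the list alone, camera adjusted p = 2.51e-12; adjusted p = 0.101 with an estimated correlation). In all 7376 genes passed, 2283 higher and 5093 lower, of which 788 and 1656 at least 2-fold. The share of higher genes among those past the threshold was 30.9% as listed and 50.4% after scaling, with the medians -0.24 apart.

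Vim-KO against WT with PBS asks how the lines differ at rest. Besides Vim (17.8 ± 1.19 against 1904 ± 37.6 TPM, -6.66 ± 0.069, adjusted p = 1.01e-09) the knockout cells had far lower levels of several macrophage transcripts. The lipid scavenger receptor Cd36 was listed at 0 in both Vim-KO libraries and at 440.5 and 438 TPM in WT. Lyz1 (16.964 ± 1.86 against 3159 ± 45.6 TPM, log2 fold change -7.46 ± 0.074, adjusted p = 1.01e-09), a lysozyme, Cxcl16 (0.0293 ± 0.0415 against 158 ± 5.35 TPM, log2 fold change -7.27 ± 0.092, adjusted p = 3.4e-09), a chemokine and scavenger receptor, were also far lower, as were Basp1 (0.104 ± 0.0737 against 40.2 ± 2.83 TPM, log2 fold change -5.22 ± 0.096) and Flot2 (0.0365 ± 0.0516 against 25.5 ± 0.859 TPM, log2 fold change -4.68 ± 0.11), a membrane raft protein. Higher were Angptl2 (144 ± 0.478 against 10.7 ± 0.586 TPM, log2 fold change 3.62 ± 0.086, adjusted p = 1.73e-07), a secreted angiopoietin-like protein, Cd24a (168 ± 11.5 against 13.2 ± 1.18 TPM, log2 fold change 3.58 ± 0.099), a surface glycoprotein, and Smo (21.8 ± 1.95 against 0.245 ± 0.0739 TPM, log2 fold change 4.20 ± 0.17), the Hedgehog signal transducer. Tgm2 was lower (0.0511 ± 0.000429 against 3.29 ± 0.06002 TPM, adjusted p = 2.97e-05).

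Every type I interferon-stimulated gene was lower in Vim-KO cells with PBS: 34 of 34 were lower (34 adjusted over the list alone, camera adjusted p = 1.47e-21; adjusted p = 0.0465 with an estimated correlation). Rtp4 (4.94 ± 0.391 against 63.8 ± 4.38 TPM) and Oas2 (8.01 ± 1.2 against 63.9 ± 1.82 TPM) were lower in Vim-KO cells. Of the immunoproteasome and MHC class I list 16 of 17 were lower and 1 did not pass (16 adjusted over the list alone, camera adjusted p = 1.89e-08; adjusted p = 0.136 with an estimated correlation). H2-D1 (274 ± 11.99 against 743 ± 8.803 TPM) was lower in Vim-KO cells. Macrophage identity genes were lower as well, where 12 were lower and 4 did not pass (15 adjusted over the list alone, camera adjusted p = 2.96e-05; adjusted p = 0.306 with an estimated correlation). Adgre1 (26.7 ± 2.84 against 90.3 ± 1.42 TPM), the F4/80 antigen, was lower in Vim-KO cells. In the p53 list 15 of 19 were lower and 4 did not pass (16 adjusted over the list alone, camera adjusted p = 4.84e-06; adjusted p = 0.203 with an estimated correlation). In the lysosome list 1 of 33 was higher, 25 were lower and 7 did not pass (1 and 25 adjusted over the list alone, camera adjusted p = 7.51e-07; adjusted p = 0.351 with an estimated correlation). Lipa (229 ± 12.6 against 601 ± 12.2 TPM) was lower and Gpnmb (408 ± 16.8 against 72.2 ± 0.537 TPM) higher. Of 25 endoplasmic reticulum chaperone genes 4 were higher and 4 lower, but other chaperones were higher. Of the heat shock genes 14 of 20 were higher, 1 was lower and 5 did not pass (15 and 1 adjusted over the list alone, camera adjusted p = 4.91e-06; adjusted p = 0.136 with an estimated correlation). Of the TRiC chaperonin and prefoldin genes 10 of 13 were higher and 3 did not pass (10 adjusted over the list alone, camera adjusted p = 1.8e-04; adjusted p = 0.136 with an estimated correlation). Hsp90aa1 (1457 ± 20.02 against 768 ± 50.8 TPM) and Cct3 (643 ± 1.04 against 481 ± 3.65 TPM) were higher in Vim-KO cells. Of the constitutive proteasome genes 17 of 33 were higher, 1 was lower and 15 did not pass (17 and 1 adjusted over the list alone, camera adjusted p = 6.07e-06; adjusted p = 0.238 with an estimated correlation). In all 4782 genes passed, 1962 higher and 2820 lower, 233 and 736 at least 2-fold, and the share of higher genes past the threshold was 41.0% as listed and 48.0% after scaling. The labels do not distinguish separate Vim-KO lines, so the loss of Vim and other differences between the lines stand together.

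Vim-KO against WT with LPS asks how the activated lines differ. The cytokine antagonist Il1rn (18.1 ± 0.116 against 2618 ± 223 TPM, log2 fold change -7.09 ± 0.097, adjusted p = 6.69e-09) and the chemokine Ccl7 (7.53 ± 0.126 against 584 ± 36.7 TPM, log2 fold change -6.10 ± 0.094, adjusted p = 1.1e-08) were among the lowest, with Serpinb2 at 0.095 and 0.186 TPM in Vim-KO and 206 and 217 TPM in WT, and Cd36 at 0.036 and 0 TPM against 641 and 698 TPM. The highest were Plod2 (126 ± 2.302 against 3.56 ± 0.0737 TPM, log2 fold change 4.80 ± 0.088, adjusted p = 2.95e-08), which hydroxylates collagen lysines, Itga3 (31.014 ± 1.32 against 0.569 ± 0.0415 TPM, log2 fold change 4.35 ± 0.13), an integrin chain, Batf (147 ± 6.37 against 7.1022 ± 0.267 TPM, log2 fold change 4.20 ± 0.10), an AP-1 family factor, and Ctsh (250.0 ± 5.43 against 14.2 ± 3.104 TPM, log2 fold change 4.06 ± 0.13), a lysosomal protease. Vim was 31.9 ± 1.55 against 1418 ± 61.2 TPM and Tgm2 0.47984 ± 0.0996 against 3.25 ± 0.196 TPM (adjusted p = 1.41e-04).

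Of the inflammatory cytokines and chemokines 3 of 26 were higher, 19 were lower and 4 did not pass (3 and 19 adjusted over the list alone, camera adjusted p = 3.75e-09; adjusted p = 0.27 with an estimated correlation). Cxcl3 (0.577 ± 0.0931 against 105 ± 5.54 TPM) and Il33 (3.72 ± 0.0522 against 131 ± 17.1 TPM) were lower in Vim-KO cells. Genes of the inflammasome list, of which 3 were higher, 9 were lower and 4 did not pass (3 and 9 adjusted over the list alone, camera adjusted p = 4.64e-03; adjusted p = 0.348 with an estimated correlation), included lower Il1b (559.5 ± 9.95 against 2749.5 ± 34.1 TPM, log2 fold change -2.29 ± 0.07, adjusted p = 4.15e-07), Il18 (14.7 ± 0.589 against 45.9 ± 3.51 TPM) and Casp1 (73.7 ± 4.3 against 136 ± 3.18 TPM). Within classical activation 1 of 17 was higher, 12 were lower and 4 did not pass (1 and 12 adjusted over the list alone, camera adjusted p = 8.01e-05; adjusted p = 0.27 with an estimated correlation). In the lysosome list 1 of 33 was higher, 23 were lower and 9 did not pass (1 and 25 adjusted over the list alone, camera adjusted p = 2.43e-08; adjusted p = 0.435 with an estimated correlation). Heat shock genes stayed higher, where 13 were higher, 2 were lower and 5 did not pass (13 and 2 adjusted over the list alone, camera adjusted p = 3.13e-04; adjusted p = 0.27 with an estimated correlation), with Hspa4l (85.5 ± 6.31 against 30.6 ± 0.586 TPM). The TRiC chaperonin and prefoldin did so too, where 9 were higher and 4 did not pass (9 adjusted over the list alone, camera adjusted p = 6.01e-03; adjusted p = 0.27 with an estimated correlation). Of the glycolysis and hypoxia list 22 of 25 were higher, 1 was lower and 2 did not pass (24 and 1 adjusted over the list alone, camera adjusted p = 1.98e-10; adjusted p = 0.348 with an estimated correlation). Adm (25.4 ± 2.63 against 2.29 ± 0.211 TPM) and Pdk1 (64.3 ± 5.85 against 16.992 ± 1.72 TPM) were higher and Pfkfb3 (9.44 ± 1.44 against 70.1 ± 6.14 TPM) lower. Type I interferon-stimulated genes differed less with LPS, where 15 were higher, 3 were lower and 16 did not pass (16 and 3 adjusted over the list alone, camera adjusted p = 0.0429; adjusted p = 0.435 with an estimated correlation). That camera call ended without Vim-KO LPS replicate 2 (adjusted p = 0.0559), with scaling (adjusted p = 0.0505) and with a pseudocount of 0.1 (adjusted p = 0.0506). In all 4966 genes passed, 2681 higher and 2285 lower, 346 and 570 at least 2-fold. The share of higher genes past the threshold was 54.0% as listed and 44.4% after scaling.

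The interaction tests directly whether the LPS response differed between the lines, as the Vim-KO change minus the WT change. A positive value is a larger rise or a weaker fall in Vim-KO cells, so its sign does not give the size of the response. Interferon genes rose more in Vim-KO cells, at 3.58 ± 0.15 for Mx2 (adjusted p = 1.4e-05), 3.45 ± 0.11 for Rtp4 (adjusted p = 3.46e-06) and 3.17 ± 0.15 for Oas2 (adjusted p = 1.9e-05). Reads of Mx1 (3.69 ± 0.20) and Mx2 may be shared. Genes that rose less, or did not pass, in Vim-KO cells were the chemokine Cxcl3 (-6.14 ± 0.19, adjusted p = 3.46e-06), the alarmin S100a8 (-5.52 ± 0.30), Serpinb2, Il33 and the cytokine Il10. Il10 was 24.8 and 27.5 TPM in WT cells with LPS and listed at 0 in all Vim-KO libraries, and Il33 was 119 and 143 TPM against 3.76 and 3.69 TPM. Vim itself differed (1.23 ± 0.098, adjusted p = 1.45e-04), while Tgm2 did not pass (adjusted p = 0.135).

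All 34 type I interferon-stimulated genes had a positive value and the larger absolute LPS change in Vim-KO cells, with a median difference of 2.23 (camera adjusted p = 3.4e-31; adjusted p = 0.0227 with an estimated correlation, and 34 adjusted over the list alone). Of the immunoproteasome and MHC class I list 15 of 17 had a positive value and 2 did not pass (17 adjusted over the list alone, camera adjusted p = 7.9e-09; adjusted p = 0.144 with an estimated correlation), as for Tap1 (1.58 ± 0.14). In the p53 list 17 of 19 were positive, 1 negative and 1 did not pass (17 and 1 adjusted over the list alone, camera adjusted p = 3.79e-09; adjusted p = 0.144 with an estimated correlation), with Trp53inp1 at 2.55 ± 0.23. For the inflammatory cytokines and chemokines 3 of 26 were positive, 17 negative and 6 did not pass (3 and 18 adjusted over the list alone, camera adjusted p = 7.48e-12; adjusted p = 0.11 with an estimated correlation). Of the constitutive proteasome genes 1 of 33 was positive, 9 were negative and 23 did not pass (1 and 16 adjusted over the list alone, camera adjusted p = 3.95e-09; adjusted p = 0.192 with an estimated correlation), or 0 positive and 18 negative after scaling, with Psma6 at -0.82 ± 0.083 and Psmd3 at -0.52 ± 0.089. In the ATF4 and amino acid response 4 of 26 were positive, 11 negative and 11 did not pass (4 and 13 adjusted over the list alone, camera adjusted p = 6.29e-04; adjusted p = 0.573 with an estimated correlation; adjusted p = 0.206 with fry). In all 2292 genes passed, 1518 positive and 774 negative. The absolute LPS change was larger in Vim-KO cells for only 609 of the positive and 375 of the negative genes. Of the 2292, 1166 were past the threshold the same way in both lines, 223 in opposite ways, 361 in Vim-KO cells alone and 537 in WT cells alone. The count was 1219 without WT PBS replicate 1, 1249 without WT PBS replicate 2, 1458 without WT LPS replicate 1, and 1448 and 1234 without Vim-KO PBS replicates 1 and 2. The share of positive values among genes past the threshold was 66.2% as listed and 46.1% after scaling, with the medians 0.12 apart.

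**Figure D3:**
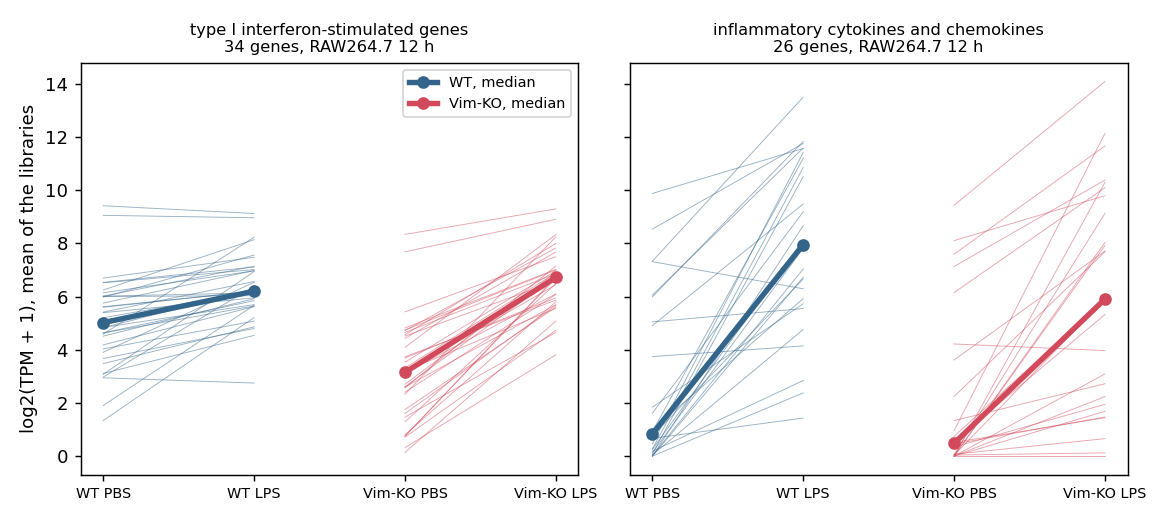
Levels on a log2(TPM + 1) scale of type I interferon-stimulated genes (34) and of inflammatory cytokines and chemokines (26) in the 4 groups of the 12 h experiment; thin lines are genes and the thick line is the median of the list. The LPS change of the interferon list has a median of 1.13 in WT and 3.43 in Vim-KO cells.

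Whether genes that differ with CTM also differ between Vim-KO and WT cells was read by setting LPS plus CTM against LPS (24 h) beside Vim-KO against WT with LPS (12 h), which share no library. Of genes past both thresholds 644 were higher in both and 414 lower in both, where independent lists would share 433.2 and 208.2 (406 and 635 after scaling, where they would share 261.1 and 385.1). Another 282 and 220 moved in opposite ways, where independent lists would share 363.5 and 248.1. Across 10797 genes Pearson's r was 0.169 and Spearman's rho 0.157. For LPS against PBS at 24 h and at 12 h in WT cells r was 0.67 and rho 0.561, with 4815 genes past both thresholds the same way and 754 in opposite ways. Levels of the 24 h and 12 h experiments were not tested against each other, since time and batch differ together.

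Every gene of the liver values had a WT LPS to PBS ratio of at least 2 (1459 genes) or at most its inverse (3839 genes). The values are thus a selection on that pair, and its WT LPS against PBS count is circular. Of the genes listed 4099 had a mean of at least 1 TPM, and a log2 difference of at least 1 was counted. Vim was not listed for liver at all, so its level there is unknown. With PBS and LPS in WT liver, 1058 genes were higher and 2238 lower with LPS. The balance turned with scaling, from 32.1% to 76.9% higher. The acute phase proteins Saa3 (5776 against 18.1 TPM) and Lcn2 (17187 against 56.9 TPM) and the chemokine Cxcl9 (2636 against 12.7 TPM) were far higher. The glucose-6-phosphatase gene G6pc (2.0 against 189.9 TPM), the rate-limiting bile acid enzyme Cyp7a1 (0.13 against 35.8 TPM) and Hhex (0.54 against 61.8 TPM), a hepatocyte transcription factor, were lower. Percentiles place the median of a list among 10000 random lists matched on expression. For inflammatory cytokines and chemokines 19 of 20 were higher, 0 lower and 1 between (median log2 difference 4.53, percentile 100). For liver sinusoidal endothelial markers 1 of 13 was higher, 11 lower and 1 between (median log2 difference -1.89, percentile 0.16), as for Kdr (0.07 against 7.97 TPM), and for neutrophil markers 8 of 8 were higher, 0 lower and 0 between (median log2 difference 2.57, percentile 99.99), as for S100a9 (34.8 against 0.22 TPM). Monocyte markers had 8 higher and 1 lower of 9, median 1.64, percentile 99.91.

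LPS plus CTM against LPS in liver gave 37 higher and 45 lower genes. A pseudocount of 0.1 gave 264, and scaling 125 (25.6% higher against 45.1%). Higher were Etnppl (68.3 against 8.95 TPM, log2 difference 2.80), an ethanolamine-phosphate lyase, the inducible chaperone Hspa1b (10.2 against 0.93 TPM, log2 difference 2.54), Cth (94.5 against 28.4 TPM, log2 difference 1.70), which makes cysteine, and Alas1 (180.3 against 68.6 TPM, log2 difference 1.38), the first enzyme of haem synthesis. Lower were Rgs16 (8.29 against 64.8 TPM, log2 difference -2.83), the sterol sensor Insig1 (6.23 against 29.1 TPM, log2 difference -2.06) and Nos2 (3.36 against 15.5 TPM, log2 difference -1.92). For p53 targets 0 of 17 were higher, 4 lower and 13 between (median log2 difference -0.71, percentile 0), with Btg2 (156 against 380.3 TPM). For cholesterol biosynthesis 0 of 13 were higher, 3 lower and 10 between (median log2 difference -0.64, percentile 0). Cytokines and chemokines had 0 higher and 1 lower of 20, median -0.23, percentile 0.83, with Cxcl2 (51.8 against 92.6 TPM), and the ATF4 response had 1 higher and 0 lower of 15, median 0.28, percentile 99.74, with Asns (6.44 against 2.77 TPM). Marker medians lay outside the central range of random lists for neutrophils (8 members, 1 higher, median 0.40, percentile 99.59). With none past the threshold, so did those of Kupffer cells (11, 0.36, 99.62), monocytes (9, 0.42, 99.88), macrophage identity (9, 0.30, 98.4) and erythrocytes and platelets (6, -0.58, 0.01). WT LPS livers of different dates, without CTM, differed in 391 genes. Cytokine, Kupffer and erythrocyte lists moved more there, p53, cholesterol and ATF4 less. With 1 library each, no shift is ascribed to CTM. Tgm2 was 429 against 424.8 TPM.

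LPS plus CTM against PBS in liver gave 905 higher and 2006 lower genes, on the selection made with the PBS library. The share higher turned from 31.1% to 78.1% with scaling. Saa2 (18767 against 68.9 TPM), Lcn2 (18312 against 56.9 TPM) and the antiviral Rsad2 (796 against 3.59 TPM) were among the highest, and G6pc (1.33 against 189.9 TPM), Hsd3b5 (2.13 against 188 TPM) and the clock output gene Dbp (1.91 against 101 TPM) among the lowest. For acute phase proteins 21 of 24 were higher, 0 lower and 3 between (median log2 difference 2.77, percentile 99.99), and for fatty acid oxidation and ketogenesis 1 of 12 was higher, 9 lower and 2 between (median log2 difference -1.43, percentile 1.71), with Ppara (9.25 against 38.7 TPM) lower. Markers of neutrophils (8 higher and 0 lower of 8, median 3.34, percentile 100), monocytes (8 higher and 0 lower of 9, median 2.06, percentile 100) and sinusoidal endothelium (1 higher and 10 lower of 13, median -1.61, percentile 1.25) moved too.

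Macrophage depletion before LPS asks which liver transcripts differ when macrophages are depleted, with 1 library on each side. The Kupffer cell markers Clec4f (0.21 against 12.3 TPM, log2 difference -3.46), C1qc (2.24 against 32.9 TPM, log2 difference -3.39) and Vsig4 (0.12 against 6.42 TPM, log2 difference -2.73) were lower, and for that list 0 of 11 were higher, 9 lower and 2 between (median log2 difference -2.35, percentile 0). For cytokines and chemokines 0 of 20 were higher, 14 lower and 6 between (median log2 difference -1.74, percentile 0), including Il1a (0.96 against 20.6 TPM, log2 difference -3.46), Il1b (2.34 against 23.1 TPM) and Ccl5 (24.3 against 209 TPM). Classical activation genes had 1 higher and 10 lower of 16, median -1.35, percentile 0, with Acod1 (5.41 against 26.9 TPM), and p53 targets 0 higher and 13 lower of 17, median -1.35, percentile 0, with Gdf15 (9.72 against 51.7 TPM). For acute phase proteins 8 of 24 were higher, 0 lower and 16 between (median log2 difference 0.73, percentile 100), with Orm2 (8083 against 1085 TPM, log2 difference 2.90) and Hp (18202 against 7577 TPM). Gluconeogenesis and amino acid catabolism had 3 higher and 0 lower of 8, median 0.65, percentile 99.84, with G6pc (26.6 against 2.47 TPM). Neutrophil (2 higher and 1 lower of 8, median 0.55, percentile 99.91), sinusoidal endothelial (2 higher and 0 lower of 13, median 0.60, percentile 99.99) and monocyte (0 higher and 5 lower of 9, median -1.09, percentile 0.01) markers and erythrocyte and platelet transcripts (0 higher and 0 lower of 6, median -0.73, percentile 1.27) had medians outside the central range too. Des (24.5 against 0.36 TPM, log2 difference 4.23) and Pygm (10.7 against 0.19 TPM), both typical of muscle, were higher, and Des stands in the stellate cell list (2 higher and 0 lower of 6, median 0.66, percentile 99.93). In all 129 genes were higher and 321 lower with depletion (687 in total with a pseudocount of 0.1), and Tgm2 was 351 against 382 TPM.

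**Figure D4:**
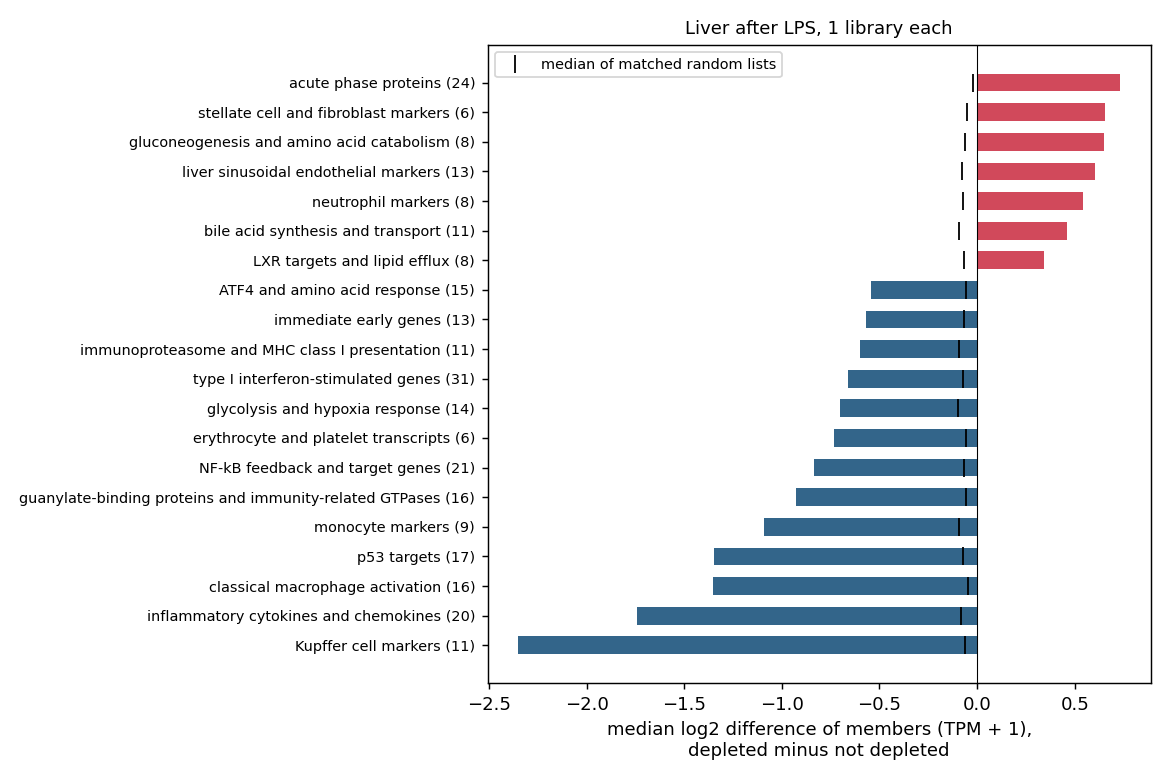
Median log2 difference of list members in liver after LPS, macrophage-depleted minus not depleted (1 library each), for lists outside the central range of matched random lists, with the random median as a vertical mark. The Kupffer cell list lies at -2.35 and the acute phase list at 0.73.

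LPS against PBS in TG2-KO liver gave 764 higher and 875 lower genes, 46.6% higher (79.8% scaled). Genes were selected on the WT pair, so a lower count than in WT is built in. Cxcl9 (1629 against 3.16 TPM, log2 difference 8.61), Saa3 (3277 against 6.46 TPM, log2 difference 8.78) and Rsad2 (732 against 1.26 TPM) were among the highest and Cyp7a1 (0.39 against 21.9 TPM, log2 difference -4.04), Inhbe (0.24 against 22.2 TPM) and Gpam (2.6 against 30.9 TPM) among the lowest. For type I interferon-stimulated genes 31 of 31 were higher, 0 lower and 0 between (median log2 difference 4.005, percentile 100), with Ifit1 (983 against 3.02 TPM). For cytokines and chemokines 18 of 20 were higher, 0 lower and 2 between (median log2 difference 2.98, percentile 100), and for bile acid synthesis and transport 0 of 11 were higher, 6 lower and 5 between (median log2 difference -1.14, percentile 0.07). Haemoglobin and platelet transcripts were higher with LPS (5 higher and 0 lower of 6, median 3.26, percentile 99.96), with Hba-a1 (1113 against 110.4 TPM), and neutrophil markers too (7 higher and 0 lower of 8, median 1.93, percentile 99.98). Monocyte markers had 6 higher and 0 lower of 9, median 1.36, percentile 99.86, and sinusoidal endothelial markers 1 higher and 8 lower of 13, median -1.34, percentile 0.02.

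TG2-KO against WT compares libraries of different extraction dates, so genotype and date cannot be told apart. The genes were also selected on these WT libraries, which puts another PBS library nearer to LPS and another LPS library nearer to PBS. With PBS 154 genes were higher and 214 lower in TG2-KO liver (628 in total with a pseudocount of 0.1). Scaling turned the share higher from 41.8% to 76.8%. Besides Tgm2, Ahcy (34.3 against 1222 TPM, log2 difference -5.12), which hydrolyses S-adenosylhomocysteine, was lower, and Saa1 (1172 against 22.2 TPM, log2 difference 5.66), Cxcl1 (85.5 against 3.04 TPM, log2 difference 4.42) and Orm2 (214 against 14 TPM, log2 difference 3.84) were higher. For acute phase proteins 18 of 24 were higher, 1 lower and 5 between (median log2 difference 1.48, percentile 100), with Mt2 (3210.5 against 254 TPM). Neutrophil markers had 4 higher and 0 lower of 8, median 0.86, percentile 100, with S100a9 (12.2 against 0.22 TPM), Kupffer cell markers 1 higher and 2 lower of 11, median -0.75, percentile 0.02, and erythrocyte and platelet transcripts 0 higher and 4 lower of 6, median -2.51, percentile 0, with Hba-a2 (80.2 against 575 TPM). Sinusoidal endothelial markers had 0 higher and 2 lower of 13, median -0.54, percentile 1.64. Reads of Saa1 and Saa2 may be shared.

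With LPS 221 genes were higher and 105 lower in TG2-KO liver (633 in total with a pseudocount of 0.1), where genotype, date and selection again cannot be told apart. Ahcy (23.9 against 603 TPM, log2 difference -4.60), Serpina3f (86.9 against 602 TPM, log2 difference -2.78) and Cyp2b10 (0.49 against 18.6 TPM, log2 difference -3.72), a drug-metabolising enzyme, were lower, and Noct (80.1 against 8.72 TPM, log2 difference 3.06), a circadian phosphatase, Lgals1 (23.9 against 3.14 TPM, log2 difference 2.59), a galectin, and Fitm1 (55.8 against 8.63 TPM, log2 difference 2.56), a lipid droplet protein, were higher. For cholesterol biosynthesis 7 of 13 were higher, 0 lower and 6 between (median log2 difference 1.05, percentile 100), with Mvk (5.74 against 0.47 TPM), Sqle (21.1 against 4.0 TPM) and Idi1 (16.4 against 3.58 TPM). For cytokines and chemokines 0 of 20 were higher, 4 lower and 16 between (median log2 difference -0.49, percentile 0), with Csf3 (11.5 against 38.1 TPM) and Cxcl2 (29.9 against 92.6 TPM). Endoplasmic reticulum chaperones had 0 higher and 2 lower of 9, median -0.78, percentile 0.02, with Dnajb9 (50.2 against 159 TPM). Erythrocyte and platelet transcripts (0 higher and 4 lower of 6, median -1.23, percentile 0) and markers of neutrophils (2 higher and 0 lower of 8, median 0.57, percentile 98.2) and monocytes (1 higher and 1 lower of 9, median -0.26, percentile 1.5) had medians outside the central range too. Of the genes counted 67.8% were higher as listed and 21.1% after scaling.

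WT LPS libraries of different extraction dates give a yardstick for such differences, although the labels give no LPS dose for the earlier one. Between the not depleted LPS library and the LPS library of the CTM experiment 308 genes were higher and 83 lower (869 in total with a pseudocount of 0.1), without a difference in genotype but with the same selection. That direction turned with scaling, from 78.8% to 14.5% higher, and the median of all genes from 0.3 to -0.207. Cytokines and chemokines had 0 higher and 6 lower of 20, median -0.59, percentile 0, with Cxcl2 (31.5 against 92.6 TPM), endoplasmic reticulum chaperones 0 higher and 1 lower of 9, median -0.56, percentile 0.78, and type I interferon-stimulated genes 0 higher and 9 lower of 31, median -0.48, percentile 0, with Ifit1 (96.02 against 442 TPM). Kupffer cell markers had 5 higher and 0 lower of 11, median 0.98, percentile 99.97, with Cd5l (17.6 against 4.65 TPM), and erythrocyte and platelet transcripts 0 higher and 4 lower of 6, median -1.97, percentile 0, with Hba-a1 (597 against 2904 TPM).

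Between the cell line at 24 h and WT liver, 3151 genes could be compared for LPS. Of 741 genes higher in the cells, 421 were higher by the threshold in liver and 200 lower, which is 56.8% higher against 24.7% of all shared genes. Of 1471 genes lower in the cells, 963 were lower in liver and 186 higher, which is 65.5% lower against 53.5% of all shared genes. These shares are unscaled, and scaling turns the balance of directions in liver and moves it in the cells.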

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

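The tests of scaling between the Vim-KO and WT lines, of raised interferon genes in the WT PBS cells, and of a single WT PBS library were chosen only after their results were seen. The differences named first were picked out because the response to LPS differed between the WT and Vim-KO lines at 12 h by the interaction test of limma. In all 2292 genes passed that test, and 11 gene lists with the preset correlation of camera, of which 1 passed with an estimated correlation.

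Values are the Vim-KO minus the WT log2 change. Mx2 (3.58), Rtp4 (3.45), the GTPases Igtp (1.81) and Irgm2 (1.74), and Atf3 (2.74) rose in both lines and rose more in Vim-KO cells. Mx1 (3.69), Oas2 (3.17), Ddit4 (1.95) and the antigen presentation gene Tap1 (1.58) rose in Vim-KO cells and did not pass in WT cells. Atf3 and Ddit4 differ from most of their ATF4 list, in which 4 of 26 genes were positive and 11 negative. The antigen presentation gene H2-Q4 (1.09) and the p53 targets Trp53inp1 (2.55) and Eda2r (2.53) rose in Vim-KO and fell in WT cells. Hpgd (4.17) changed by -4.49 in WT and did not pass in Vim-KO cells (-0.32). Genes that rose less in Vim-KO cells, or did not pass there, were Serpinb2 (-7.54), Cxcl3 (-6.14), S100a8 (-5.52), Il33 (-4.77), Il10 (-4.71), Psma6 (-0.82) and Psmd3 (-0.52) of the proteasome, and Zyx (-1.30) and Actg1 (-0.96) of the actin cytoskeleton. The immediate early gene Egr1 (-2.74) rose in WT and fell in Vim-KO cells. The S phase genes Cdc6 (-0.97) and Rrm2 (-0.95) and the G2 and M phase genes Ccna2 (-0.92) and Cdca8 (-0.68) fell in both lines and fell more in Vim-KO cells. Exosc6 (-4.5) fell in Vim-KO cells alone, as it was above 0 only in the Vim-KO PBS libraries. Vim itself differed by 1.23. Vim also changed by 0.78 with LPS in the 24 h experiment and by -0.43 in WT cells of the 12 h experiment, a difference that was not tested, since time and batch differ together.

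The larger interferon response of Vim-KO cells was mostly a lower start: with PBS all 34 type I interferon-stimulated genes were below WT. After scaling the median difference was -1.809 with PBS and 0.165 with LPS. A single WT PBS library as the source was argued against, since 34 of 34 genes kept a positive difference past the threshold without either WT PBS replicate 1 or WT PBS replicate 2 (medians 2.16 and 2.19). Raised interferon genes in the WT PBS cells of the 12 h experiment stay open. On a scale from the Vim-KO PBS level (0%) to the WT PBS level (100%), the WT PBS cells of the 24 h experiment had a median of 36.3% (quartiles 22.5% and 54.8%), and 23 of 34 genes lay nearer to Vim-KO. These levels come from different experiments and were not tested. The state of the WT cells and loss of Vim stay open.

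The number of genes that differ between the lines with PBS (4782) was weighed against explanations other than Vim. Median-of-ratios scaling did not lower it, with 4907 genes. Chromosome explained 4.25% of the variance of these genes' changes, above the 0.91% that was the highest of 100 permutations, with the largest median on chromosome 12 (0.60 over 277 genes). Variance weighs the size of changes, so whole-chromosome copy number stays open for the count (chromosome 2: -0.39 over 369 genes). Deletions as the source of the 9 genes lost altogether (under 0.1 TPM in Vim-KO against at least 5 TPM in WT) cannot be told apart from silencing, since 22.2%, or 2 of 9, had another lost gene as direct neighbour and 9 are too few.

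The liver library with LPS plus CTM lay toward PBS from the LPS library, by a median of 6.5% of the LPS to PBS distance, with 63.0% of 3296 genes toward PBS. A candidate explanation is the selection of the listed genes on those WT libraries, which puts any other LPS library nearer to PBS. The WT LPS library of another date, without CTM, lay 24.9% toward PBS with 83.4% of genes. The CTM library thus moved less than a library that received no CTM. An effect of CTM stays open for the genes raised by LPS, where the medians were 8.6% and 13.6%, and for those lowered, where they were 5.2% and 30.5%.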

How the results depend on the processing

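The test of scaling on the relations between comparisons and the replicate block at 24 h were chosen only after the results were seen, and all other alternatives were chosen earlier. For genes named in the cell line, 14453 of 15275 values under alternatives kept their direction and side of the threshold, 819 kept the direction without passing, and 3 reversed. With scaling Cd74 turned to 0.10 and Tcp1 to 0.017 in WT cells with LPS at 12 h, as scaling moves the median of all genes there. Adm turned to -0.087 in the interaction with a pseudocount of 0.1, and the cause was not tested. Of 289 values for counts, lists and correlations 241 held and 48 moved, each given here.

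Asking for a log2 change of at least 1 left 2296, 254 and 1229 genes at 24 h (LPS, CTM against LPS, CTM against PBS). At 12 h it left 2712 (WT), 2444 (Vim-KO), 969 and 916 (Vim-KO against WT with PBS and with LPS) and 710 (interaction), fewer by construction. Lists past camera with an estimated correlation numbered 0, 0 and 0 at 24 h and 6, 5, 1, 0 and 1 at 12 h, in the same order, against 19, 19 and 19 and 18, 20, 20, 14 and 11 with the preset correlation. With an estimate the test is wider by construction. Fry gave 29 lists for WT cells with LPS and 24 for Vim-KO against WT with LPS, and the cause was not tested.

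Without 1 library, where the lone library of its group is assumed to vary like the others, the count ranged from 1094 to 2330 for CTM against LPS and from 1219 to 2649 for the interaction. For CTM it fell past 1.5 times without LPS library 3 (1680) and without CTM library 2 (1525) or 3 (1094). For the interaction it did so without WT PBS replicate 1 (1219) or 2 (1249), WT LPS replicate 1 (1458) and Vim-KO PBS replicate 1 (1448) or 2 (1234). Fewer samples are fitted then. The other counts of genes ranged within 1.5 times of their values, from 6050 to 7048 (LPS at 24 h), 4166 to 6035 (CTM against PBS), 6800 to 8208 (WT), 6293 to 7270 (Vim-KO), 3226 to 5323 and 3716 to 4652 (Vim-KO against WT with PBS and with LPS). With the LPS libraries split, the correlation of the LPS and CTM changes was -0.559 and -0.569, since no library is then shared. With scaling it was -0.688, and 2354 genes moved in opposite ways.

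A replicate block at 12 h gave 7677, 7169, 4393, 4603 and 1835 genes. Deviations of like-numbered libraries correlated between -0.219 and 0.0982, so a shared number marked no clear shared deviation. At 24 h the numbers in the values pair the LPS and CTM libraries, though the labels number them otherwise. A block on that pairing gave 2656 genes for CTM against LPS, with deviations correlated by -0.0312. The PBS libraries share only 1 number with the others, so their contrasts were not blocked. No cell line count of genes moved by 1.5 times with a pseudocount of 0.1, either filter, scaling, no trend, or the fit on the contrast alone (which does not apply to the interaction).

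In liver a filter at 5 TPM left 2076 genes (WT LPS), 1828 (CTM against PBS), 1023 (TG2-KO LPS) and 239 (LPS of another date), as fewer genes are counted. Scaling gave 1638, 125 (CTM against LPS) and 1579, and is a poor guide, since every gene listed was selected as changed. It moved the median of TG2-KO against WT from -0.198 to 0.1 with PBS and from 0.174 to -0.141 with LPS. A minimum difference of 2 left 930, 8, 819, 73, 429, 46, 27 and 22 genes in the order of the report, by construction. With a pseudocount of 0.1 there were 264 (CTM against LPS), 687 (depletion), 628 and 633 (TG2-KO against WT with PBS and with LPS) and 869 (LPS of another date), where low values spread more. Of 2772 values of named liver genes 2523 held and 249 moved. Read depth is unknown, so its limit on low genes cannot be given.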

Other observations

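The genes named here and the position of Ahcy were chosen only after the values were seen, and no test was chosen for them. Some genes differed at least 2-fold in the same direction with CTM (LPS plus CTM against LPS, 24 h) and between the lines (Vim-KO against WT with LPS, 12 h), 7 higher and 49 lower. Among those lower were Il1a (log2 fold change -3.10 ± 0.14 with CTM and -2.83 ± 0.12 in Vim-KO, n = 2 per group) and Il1b (-2.23 ± 0.15 and -2.29 ± 0.070), the interleukin 1 cytokines, and their antagonist Il1rn (-1.59 ± 0.12 and -7.09 ± 0.097). The chemokines Ccl2 (-1.34 ± 0.068 and -4.12 ± 0.11) and Cxcl10 (-2.20 ± 0.15 and -1.41 ± 0.17), the TNF receptor Tnfrsf1b (-1.65 ± 0.075 and -1.92 ± 0.11) and the checkpoint ligand Cd274 (-1.20 ± 0.14 and -2.13 ± 0.12) were lower in both. Higher in both were Bmf (1.70 ± 0.14 and 2.13 ± 0.15), the prolyl isomerase Fkbp11 (1.26 ± 0.11 and 1.26 ± 0.077) and the cyclooxygenase Ptgs1 (1.09 ± 0.13 and 2.21 ± 0.11).

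In the TG2-KO livers Ahcy was far lower than in WT. Ahcy lies on chromosome 2 from 155059310 to 155074497 (GRCm38), 3.06 Mb from Tgm2. Whether its level follows from its position was not tested.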
